A study of Caenorhabditis elegans with 2 samples.

How the data were processed

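Anti-GFP ChIP-seq peak lists from 2 biological replicates of whole young adult worms carrying tagged ATHP-1 were analysed, per the labels. The labels name strain OP685, which carries the unc-119(tm4063) mutation and the integrated transgene wgIs685, and sonication as the fragmentation method. Per the deposited readme text, the authors made each replicate list from 1 alignment of that replicate and 1 control alignment. They made a pooled list from the alignments of both replicates with a control, and a reproducible list from the 2 replicate lists and the pooled list, thresholded by the irreproducible discovery rate per the deposited file names. All lists came on both ce10 and ce11. The aligner, the peak caller, the threshold and the read depth are not given in the sources used here, so the precision that depth allows is unknown.

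In the deposited lists the strength of a peak is a signal score from the authors' caller, a value relative to the control that has no fixed range. These scores are the authors' own and were used only to describe, rank or filter peaks within a list. The deposited −log10 q-value of each peak was described but not used in tests, since many peaks were tied at its maximum. The position of the summit is the deposited offset in bp from the start of the peak. Peak coordinates are on ce11 unless ce10 is named and were written 1-based; no coordinates were converted between builds.

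Genes came from Ensembl release 115 on WBcel235 (ce11), and sequence from the RefSeq assembly of the same build. Only chromosomes I to V and X were used. The promoter window ran from 500 bp upstream to 200 bp downstream of any of 29314 annotated protein-coding transcript 5′ ends, and a gene with a reproducible summit in a window was called bound. Each summit received 1 of 7 classes in the order promoter, 5′ UTR, coding exon, 3′ UTR, noncoding RNA exon, intron and intergenic. Noncoding RNA genes were called bound with a summit within 200 bp.

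Chance placement was drawn by shifting all summits of a chromosome together by a random distance around the chromosome, 100000 times. Correlations used permutations of the pairing, 100000 draws for reproducible peaks and 10000 for all matched regions. The design had named 100000 for both; the smaller number was used for the larger set to limit run time. GC differences used sign flips, 100000 draws. The middle and the ends of a chromosome are its central span, one part in 3, and the remainder. Sets of genes and words of 6 bases were compared by two-sided Fisher's exact tests, with odds ratios and exact 95% intervals. Benjamini-Hochberg adjustment was made within each family of tests, and 0.05 was the threshold. The 27 gene lists were fixed before the data were examined; 16 were defined by a symbol pattern and 11 by named genes. All named symbols matched the annotation except for the intestine list, in which 14 of 15 matched. Genes were treated as independent in the exact tests.

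Genes named in the text followed a rule fixed with the lists. It takes genes with 1 of the 20 strongest reproducible summits in the promoter window; the 4 bound members with the highest signal of each list bound more often, and up to 3 of each list bound less often; athp-1 and unc-119; and bound genes of any list of named genes with 12 or fewer members. Genes outside the rule are marked in the text, except C44B9.2 and vha-6, which are named only for a position and for membership of a list.

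Alternatives fixed before the data were examined were the strongest peaks of either replicate alone, as many of the pooled list, the 825 strongest reproducible peaks, promoter windows of 200 bp to each side or 1000 bp upstream to 500 bp downstream, assignment to the nearest 5′ end only, other overlap rules, ce10 lists, windows of 101 bp, other flanks, distances of 0 and 500 bp for noncoding genes, and shifted summits in place of the exact test for gene lists. Added after seeing the data were the removal of summits at tRNA, small nucleolar and small nuclear RNA genes, and a shift of bound labels along the order of genes.

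The scripts were tested on simulated data. With randomly placed summits, the promoter share passed the threshold in 13 of 200 runs (6.50%), and with 5% of the 1649 summits moved into promoters it passed in 50 of 50. With members bound at 4 times the rate of other genes, the 81 ribosomal protein genes were called in 181 of 200 runs. The 22 heat shock genes were called in 45 of 200, so even enrichment of this size was mostly missed in a short list. An implanted word of 6 bases was called with the smallest p in 20 of 20 runs, among randomly placed windows with no GC difference built in. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9.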

Results

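The binding of ATHP-1, a protein with AT-hook and PHD finger motifs, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans. The animals expressed ATHP-1 with a carboxy-terminal GFP-FLAG tag from an integrated transgene, and the tag was captured with an antibody against GFP. They were young adults of mixed sex, collected 64 hours after starved first-stage larvae were released to grow. There was 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates, between peaks and chance placement on the genome, and between sets of genes. Each replicate list held 30000 regions with a median width of 416 bp, ordered by the signal value of the authors' peak caller. The authors' reproducible list held 1649 peaks on the ce11 genome, with a median width of 420 bp, and covered 609 kb. Its signal values ran from 105.6 to 1172, with a median of 143, and 1393 peaks shared the highest value of 3.44 for the negative log10 of q. The ce10 version of the list held 1645 peaks. The reproducible list was identical to the 1649 strongest regions of the list the authors called on both replicates together. Read depth is unknown for these lists, so no depth is given. All p-values below describe positions and genes within these lists, not the spread between animals.

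The replicates shared most of their strongest peaks, and the strongest were the same in both. Of the 1649 strongest regions of replicate 1, 1019 (61.8%, exact binomial 95% interval 59.4 to 64.1%) overlapped 1 of the 1649 strongest of replicate 2 by at least 1 bp. Among the 500 strongest of replicate 1 the share was 90.0%, and among those ranked 1001 to 1649 it was 37.4%. The peaks ranked 1, 2 and 3 were the same in the reproducible list and in each replicate: each lay at a promoter on chromosome III. Circular shifts of replicate 2 along the chromosomes gave a mean overlap of 1.39% and a maximum of 14.7% (permutation p = 1e-05, one-sided, the smallest that 100000 draws allow). Signal values were correlated across the 8656 pairs of regions whose summits lay within 100 bp (Spearman rho 0.542, permutation p = 1e-04, adjusted p = 1e-04 over 4 correlations; Pearson r of log10 signal 0.673, permutation p = 1e-04, adjusted p = 1e-04). Across the 1490 pairs at reproducible peaks, rho was 0.382 (permutation p = 1e-05, adjusted p = 2e-05) and r was 0.484 (permutation p = 1e-05, adjusted p = 2e-05). These are correlations across peaks, which are not independent replicates, and the reproducible peaks were themselves picked by the combined signal.

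**Figure D1:**
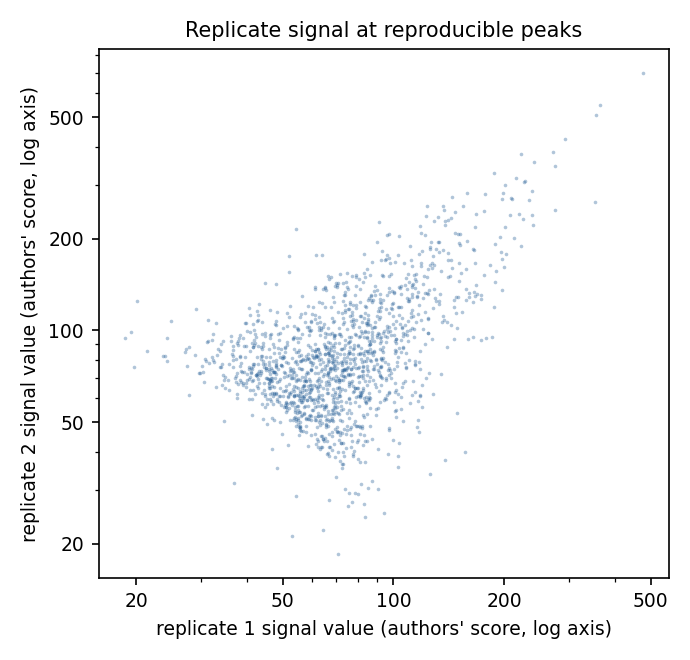
Signal value of the authors' peak caller in replicate 1 (x axis, score on a log scale) against replicate 2 (y axis, score on a log scale) for 1490 reproducible peaks with a summit within 100 bp in both lists. Each point is a peak; the strongest peaks were strong in both replicates, and rho over all points was 0.382. The empty lower left corner follows from the choice of reproducible peaks by combined signal.

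ATHP-1-GFP summits concentrated in the promoter windows of protein-coding genes. Of the 1649 reproducible summits, 783 (47.5%, exact binomial 95% interval 45.0 to 49.9%) lay from 500 bp upstream to 200 bp downstream of an annotated 5′ end, against a mean of 16.3% (SD 0.938) for summits shifted along the chromosomes (permutation p = 1e-05, two-sided, adjusted p = 1.17e-05 over 7 classes). Within this window the summits sat a median of -162 bp from the nearest 5′ end, with quartiles of -264 and -39.5 bp, and 83.4% were on the upstream side. The window itself is centred 150 bp upstream and lies mostly upstream, so its bounds largely set these values. No chance value is given for them. Exons of noncoding RNA genes held 11.6% of summits against 1.15% by shifting, and 3′ untranslated regions held 6.19% against 2.76%. Coding exons (5.40% against 21.1%), introns (8.19% against 30.3%) and intergenic sequence (20.7% against 27.8%) held smaller shares than shifted summits. Each of these 5 classes had a permutation p of 1e-05 and an adjusted permutation p of 1.17e-05. The share in 5′ untranslated regions outside the promoter windows, 0.364% against 0.510%, did not differ from chance (permutation p = 0.506). Sequence of these regions inside the windows was counted as promoter, so this value does not describe 5′ untranslated regions as a whole. The promoter share was 43.4% for the 1649 strongest regions of replicate 1 and 49.4% for those of replicate 2, a gap far smaller than the distance of either from the shifted mean. As a ratio, the replicates differed more in 2 smaller classes, with smaller gaps in points: 3′ untranslated regions held 7.76% in replicate 1 and 3.82% in replicate 2 (permutation adjusted p = 0.0146 for replicate 2 against shifting), and coding exons held 8.19% and 5.03%.

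**Figure D2:**
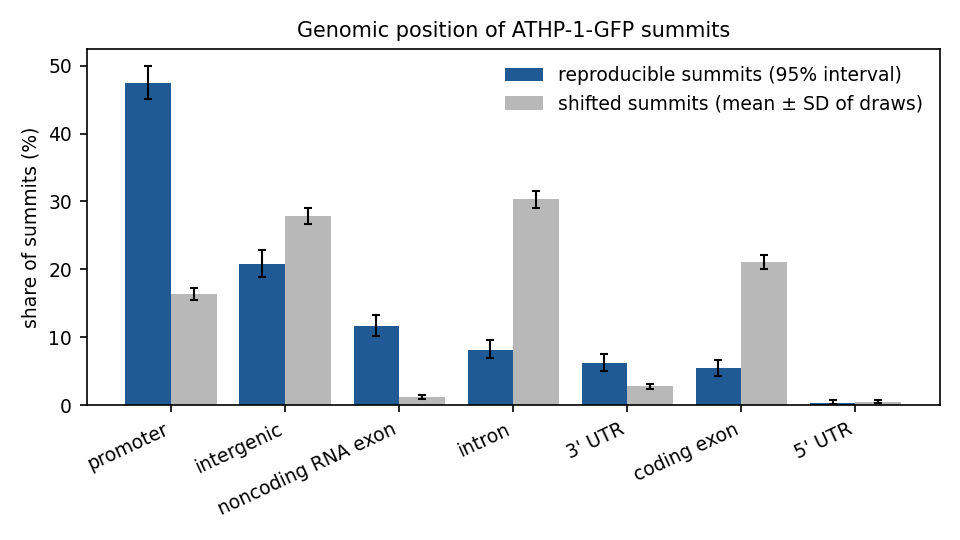
Share of summits (y axis, percent) in each annotation class (x axis) for the 1649 reproducible summits, with exact binomial 95% intervals, and for circularly shifted summits, with the SD over draws. Promoters held 47.5% of summits against 16.3% after shifting.

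**Figure D3:**
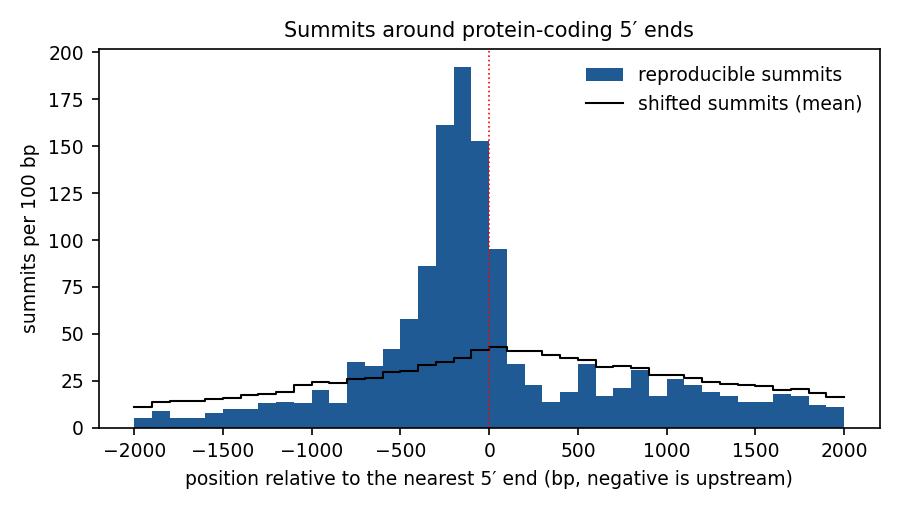
Position of reproducible summits relative to the nearest protein-coding 5′ end (x axis, bp, negative upstream) as the number of summits per 100 bp (y axis), with the mean of shifted summits as a line. Summits within the promoter window had a median of -162 bp, close to the centre of that window at 150 bp upstream.

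The 3 strongest peaks lay at the promoters of tasp-1, of set-16 with drr-2, and of the ribosomal protein gene rpl-3. The peak with the highest signal, 1172, was on chromosome III from 10759031 to 10759482 (ce11) at the promoter of tasp-1 (WBGene00010480), which encodes a taspase, a threonine protease. The next, with a signal of 909, lay on chromosome III from 13643565 to 13643932 between set-16 (WBGene00011729), an MLL-type histone H3 lysine methyltransferase gene, and drr-2 (WBGene00011730), a gene for a translation initiation factor. Of the 20 strongest summits, those at promoters also marked the ribosomal protein genes rpl-3, rpl-20, rpl-35, rpl-15 and rps-28, the AAA ATPase gene cdc-48.1, the translocon gene sec-61.G and the egg activation gene egg-4. The same rule named Y17G9B.5, Y32G9A.2, Y22D7AL.10, C15C6.3, Y39B6A.43 and K11H12.8, which are given here by their sequence names. Other strong summits were outside promoters, and these were named after their values were seen. The summit ranked 7 lay in an intron of pxn-1, within 200 bp of the small nucleolar RNA gene ZK994.7, and the summit ranked 16 lay at rpr-1, the RNase P RNA gene, inside ints-8.

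In all, 941 of 19973 protein-coding genes (4.71%) had a reproducible summit in the promoter window and are called bound. Counting the strongest summit of each, they rest on 759 distinct summits, so neighbouring genes often shared one. Of 27 gene lists, 8 were bound more often than other genes and 4 less often, by Fisher's exact test with Benjamini-Hochberg adjustment. Untagged worms, other tagged proteins and gene expression were not compared here. Whether the promoter and gene-list patterns are particular to ATHP-1 was therefore not tested. Ribosomal proteins had 31 of 81 genes bound (38.3%; odds ratio 12.9, 95% interval 7.94 to 20.8, exact test adjusted p = 1.49e-19), led by rpl-3, rpl-20, rpl-35 and rps-28. In a promoter window of 200 bp to each side their odds ratio was 4.15. Among genes of the DREAM complex and other synMuv B repressors, 6 of 11 were bound (odds ratio 24.4, 95% interval 6.19 to 101.3, exact test adjusted p = 3.65e-05). These were the Rb homolog lin-35, the E2F gene efl-1, and the MuvB core genes lin-9, lin-52, lin-53 and lin-54, with signals from 150.2 for lin-52 to 368 for lin-9. Histone methylation and heterochromatin genes had 6 of 25 members bound (odds ratio 6.42, 95% interval 2.09 to 16.8, exact test adjusted p = 0.00340). Besides set-16, the strongest were ash-2 and set-2, which encode subunits of the COMPASS H3K4 methyltransferase, and the histone demethylase gene jmjd-1.2.

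Genes of basic cell function and of the germ line were also bound more often. Mitochondrial respiration had 10 of 37 genes bound (odds ratio 7.56, 95% interval 3.25 to 16.2, exact test adjusted p = 3.78e-05), with the cytochrome c oxidase genes cox-5B, cox-5A and cox-6B and the ATP synthase gene atp-1 strongest. The odds ratio was 5.36 with replicate 1 alone (7 of 37 bound) and 11.7 with replicate 2 alone (14 of 37). Germline and oocyte genes had 8 of 34 bound (odds ratio 6.27, 95% interval 2.45 to 14.3, exact test adjusted p = 7.73e-04), among them the eggshell proteoglycan gene cpg-1, the embryonic RNA-binding protein genes mex-1 and mex-5, and egg-1, which is needed for fertilization. Cell cycle and DNA replication genes had 6 of 26 bound (odds ratio 6.10, 95% interval 2.00 to 15.8, exact test adjusted p = 0.00371), including pcn-1, the replicative helicase genes mcm-2 and mcm-4, and bir-1, a survivin homolog. Heat shock proteins had 5 of 22 bound (odds ratio 5.97, 95% interval 1.72 to 16.9, exact test adjusted p = 0.00928), with hsp-1, hsp-90, hsp-110 and hsp-3 strongest. The proteasome had 6 of 33 bound (odds ratio 4.52, 95% interval 1.52 to 11.2, exact test adjusted p = 0.0108), with the regulatory particle genes rpn-3, rpn-9, rpn-11 and rpn-2 strongest. Across the 12 lists, 4 summits were counted for 2 genes each: hsp-110 with rpn-3, lin-54 with rpl-12, and within the ribosomal list rpl-39 with rps-30 and rpl-24.1 with rps-10. The 5 ribosomal genes in these pairs were named after their values were seen, and the 31 bound ribosomal genes rest on 29 summits. The heat shock call ended when each summit was given only to its nearest 5′ end (odds ratio 2.54, exact test adjusted p = 0.287) and in a promoter window of 200 bp to each side (odds ratio 1.78, exact test adjusted p = 0.626). The narrower window also ended the calls for the proteasome and for germline and oocyte genes (odds ratios 3.76 and 3.64, exact test adjusted p = 0.130 for each), and the 825 strongest peaks alone ended those 2 calls and that for the cell cycle (odds ratios 2.46, 3.70 and 4.99, exact test adjusted p = 0.372, 0.136 and 0.0944).

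Several large gene families were seldom bound. Chemoreceptors were listed by symbol prefix alone (str, or sr with further letters), so the list may hold other genes as well. Of its 1364 genes, 5 were bound (0.367%; odds ratio 0.0695, 95% interval 0.0225 to 0.163, exact test adjusted p = 2.07e-21), with sri-5, srh-2 and srh-269 strongest. Without the summits within 200 bp of a tRNA, small nucleolar or small nuclear RNA gene, 2 remained (odds ratio 0.0296); srh-269, whose summit lay near a bound tRNA gene, was among those lost. Of 240 C-type lectin genes only clec-126 was bound (odds ratio 0.0837, 95% interval 0.00211 to 0.472, exact test adjusted p = 8.23e-04). Its summit lay between 2 bound tRNA genes, so that 0 remained without summits at small RNA genes, and with replicate 1 alone 3 were bound (odds ratio 0.286, exact test adjusted p = 0.0396). F-box genes had 6 of 322 bound (odds ratio 0.380, 95% interval 0.138 to 0.840, exact test adjusted p = 0.0273), including fbxb-72, fbxa-140 and fbxb-85. Nuclear hormone receptors had 5 of 269 bound (odds ratio 0.380, 95% interval 0.122 to 0.901, exact test adjusted p = 0.0452), including nhr-47, nhr-49 and nhr-68. The F-box and receptor calls ended when the strongest peaks of replicate 1 were used alone (exact test adjusted p = 0.0770 and 0.0507) and under 5 other alternatives each. The C-type lectin call ended with the 825 strongest peaks (exact test adjusted p = 0.106). Shifting summits along the chromosomes in place of the exact test ended all 4 calls of less binding. Chemoreceptors had 0.443 and C-type lectins 0.361 times the shifted mean (permutation adjusted p = 0.0961 and 0.578). F-box genes and nuclear hormone receptors lay above it, at 1.50 and 1.53 times (permutation adjusted p = 0.527 and 0.578). Shifting compares with random positions, not with other genes, and promoters as a whole held 2.90 times the shifted share. Lying above the shifted mean is thus not a sign of as much binding as other genes.

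The other 15 lists did not pass the test. Collagens had 2 of 156 genes bound, cytochrome P450 genes 0 of 74, histones 4 of 72, homeobox ceh genes 1 of 63 and major sperm proteins 0 of 31. Spermatogenesis-defective genes had 3 of 29 bound, meiosis genes 3 of 22, splicing proteins 3 of 15 and vitellogenins 0 of 6. Among lists of tissue markers, 1 of 14 intestine, 0 of 15 body wall muscle, 0 of 8 pharynx, 0 of 11 hypodermis and 2 of 19 neuron genes were bound, and axon guidance genes had 2 of 18. Exact test adjusted p-values ran from 0.0644 for splicing proteins to 1 for 4 of the marker and yolk lists. Even 0 of 74 cytochrome P450 genes gave an exact test p of 0.0508 before adjustment. Less binding could therefore not be called in lists of that size or smaller, whatever their counts. Upper ends of the odds ratio intervals were 5.64 for body wall muscle, 11.9 for pharynx, 8.07 for hypodermis and 17.2 for vitellogenins. Whether genes of these 4 lists were bound less often thus stays undecided. Splicing proteins passed in the wider promoter window, from 1000 bp upstream to 500 bp downstream (exact test adjusted p = 5.95e-04), and with the 825 strongest peaks (exact test adjusted p = 0.0232). Against shifted summits, splicing proteins, histones, meiosis genes and spermatogenesis-defective genes all passed (permutation adjusted p = 0.0103, 0.0391, 0.0210 and 0.0326). That comparison is with random positions, so it does not show more binding than at other genes.

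**Figure D4:**
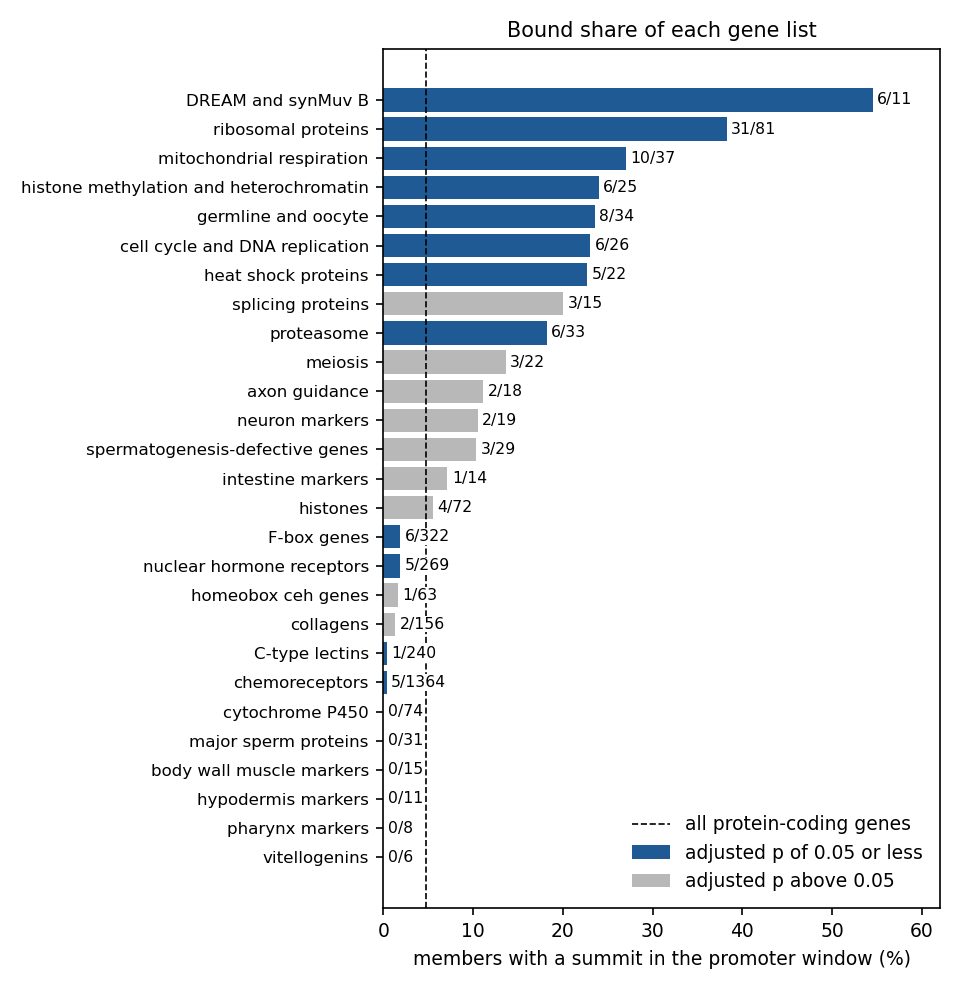
Share of each gene list's members with a reproducible summit in the promoter window (x axis, percent), with bound and total members beside each bar. The dashed line is the 4.71% of all protein-coding genes; blue bars had an adjusted p of 0.05 or less by Fisher's exact test.

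Bound protein-coding genes were rare on the X chromosome. On X, 38 of 2731 genes were bound (1.39%), against 903 of 17242 on the autosomes (5.24%), an odds ratio of 0.255 (95% interval 0.179 to 0.354, Fisher's exact test p = 1.13e-23, two-sided). Among the autosomes the share ran from 3.10% on chromosome V to 7.88% on chromosome III. The odds ratio was 0.241 with the strongest peaks of replicate 1 alone and 0.280 with those of replicate 2 alone. Along the autosomes, genes near the middle of a chromosome were bound as often as those nearer its ends, 346 of 6568 (5.27%) and 557 of 10674 (5.22%), an odds ratio of 1.01 (95% interval 0.877 to 1.16, Fisher's exact test p = 0.888).

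Small structured RNA genes formed a second class of bound sites. Of 612 tRNA genes, 257 (42.0%) had a reproducible summit within 200 bp, against a mean of 4.14 and a maximum of 32 for shifted summits. The summit lay a median of 27 bp downstream of the tRNA's 5′ end. Small nucleolar RNA genes had 72 of 346 bound, against 3.24 by shifting, and 24 small nuclear RNA genes (18.6%) were bound, against 1.08. Other noncoding RNA genes had 366 of 8058 bound against 70.4. Without summits within 200 bp of tRNA, small nucleolar or small nuclear RNA genes, 163 of them stayed bound against 53.4, so most of these genes were counted only from the same summits as those 3 classes. MicroRNA genes had 7 of 261 against 2.02 (permutation p = 0.0125, adjusted p = 0.0145 over 7 classes). Of the 7 summits near them, 3 also lay in a promoter window, as did 93 of the 308 near other noncoding RNA genes. Shifting compares with random positions, and the microRNA ratio of 3.47 was near the 2.90 of promoters. Binding at microRNA genes apart from promoters was therefore not shown. piRNA genes were bound less often than by chance, 16 of 15363 against 102 (permutation adjusted p = 4.2e-05), and 0 of 20 rRNA genes were bound (permutation p = 1). The piRNA call ended when the summit had to lie inside the gene (permutation adjusted p = 0.0716). The tRNA, small nucleolar, small nuclear and other noncoding classes each had a permutation p of 1e-05 and an adjusted permutation p of 1.75e-05. In all, 324 summits (19.6%) lay within 200 bp of a tRNA, small nucleolar or small nuclear RNA gene, and 56 of these were also in a promoter window. Removing these 324, an alternative chosen after seeing the data, left a promoter share of 54.9% and an X odds ratio of 0.191.

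**Figure D5:**
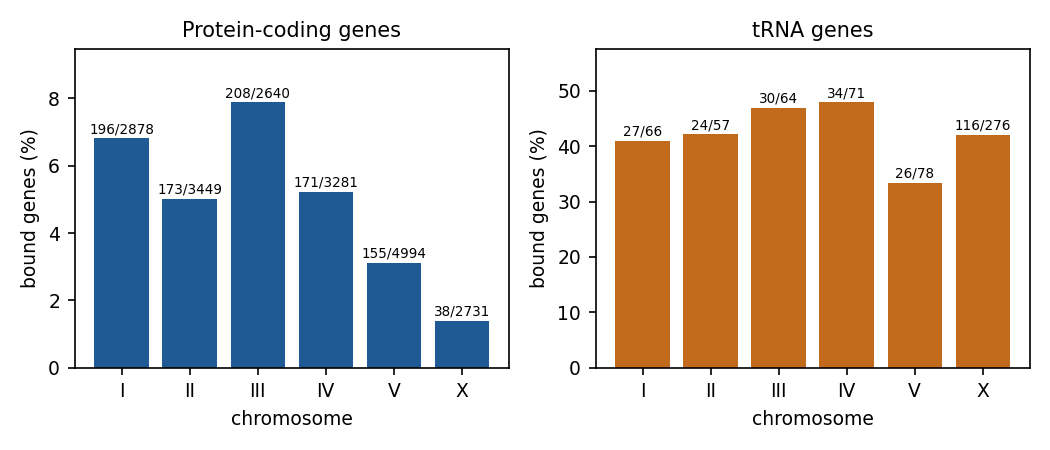
Share of genes bound (y axes, percent) on each chromosome (x axes) for protein-coding genes, left, and tRNA genes, right, with bound and total genes above each bar. On X, 1.39% of protein-coding genes and 42.0% of tRNA genes were bound.

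Sequence at the summits was richer in G and C than its surroundings. The sequence within 100 bp of a summit had a mean GC content of 42.5%, against 37.6% for windows of the same size centred 1000 bp to each side, a difference of 4.94 points (SE 0.237, n = 1649 summits, sign-flip permutation p = 1e-05, two-sided), and 66.9% of summits were higher than their flanks. Among all words of 6 bases, 1024 differed in frequency between summit and flank windows by Fisher's exact test with Benjamini-Hochberg adjustment. The test neither controlled for base composition nor used the pairing of summits with flanks. Many of these words may thus differ only through the GC difference above. The words with the smallest p were ACGCAG, present in 17.9% of summit windows and 5.00% of flank windows (exact test adjusted p = 2.61e-42), ACGCGC, in 14.9% and 3.52% (exact test adjusted p = 4.15e-41), and GCGCGC, in 10.7% and 1.61% (exact test adjusted p = 1.37e-40). GAGAGA was present in 25.2% of summit windows and 12.6% of flank windows (exact test adjusted p = 9.45e-26). CTGAAA, with its reverse complement TTTCAG, was rarer at summits, in 22.2% of windows against 36.6% (exact test adjusted p = 1.2e-23). Each word was counted together with its reverse complement, and the last 2 words were picked after their values were seen.

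The loci of the transgene were looked at separately, because extra copies can add reads there. athp-1 itself (WBGene00008081, chromosome III, 10881766 to 10893696, plus strand, ce11) was among the bound genes, with 3 reproducible summits in its promoter window, at 10881643, 10881910 and 10882148 (ranks 582, 846 and 1625). In replicate 2 the window's summits ranked 295, 470 and 678, whereas in replicate 1 they ranked 1676 and 17701, outside its 1649 strongest regions. The strongest summit within 20 kb of athp-1 was at 10877772, in an intron of the neighbouring gene C44B9.2, with rank 9 in the reproducible list, rank 9 in replicate 1 and rank 7 in replicate 2. Inside athp-1 the 30000 regions of replicate 1 included 9 summits, and those of replicate 2 included 2. unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935) had 0 reproducible summits within 5 kb, and the best-ranked region there was 15998 in replicate 2 and 21788 in replicate 1. Leaving out all peaks at the 2 loci left the same 12 gene lists past the test. This was all but fixed beforehand, since only 5 reproducible peaks lay there. The only gene with one of them in its promoter window, athp-1, is in no list.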

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

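Of the alternatives here, the removal of summits at small RNA genes and the shift of bound labels along genes were chosen after the data were seen. The promoter share, the X odds ratio, the replicate overlap and correlation, and the GC difference kept their direction and their side of the threshold under every alternative run for them, and the numbers of annotation classes, noncoding classes and words past the threshold stayed within 1.5 times. Among single noncoding classes, piRNA lost its call when the summit had to lie inside the gene. The noncoding classes are not judged by the removal of summits at small RNA genes, which takes tRNA, small nucleolar and small nuclear RNA genes to 0 by construction and left 163 of the 366 other noncoding genes bound. The X odds ratio ran from 0.170 to 0.310 and the GC difference from 3.70 to 7.65 points. As many of the strongest pooled regions as reproducible peaks gave identical values, since they are the same peaks, so that alternative tests nothing. The 825 strongest peaks left 511 bound genes and 7 gene lists past the threshold, 6 of them among the original 12. The window of 200 bp to each side left 520 bound genes and 7 lists, all among the 12. With the 825 strongest, 131 tRNA genes stayed bound. The odds ratio of chromosome centres to arms, near 1, crossed it without passing the test: 0.881 with the 825 strongest peaks, 0.943 in the narrow window, and 0.998 to 1.07 with either replicate left out.

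Of the 11 alternatives, the strongest pooled regions and the removal of peaks at the transgene loci could hardly change a gene list. Ribosomal proteins, the DREAM list, histone methylation and mitochondrial respiration stayed past the threshold under all 11. Their sizes still moved: the odds ratio of ribosomal proteins was 4.15 in the narrow window, and that of the DREAM list 14.6 by nearest 5′ end and 46.2 with the 825 strongest peaks, which also took heat shock proteins to 11.3. Without replicate 2, the strongest peaks of replicate 1 kept 10 of the 12 lists and lost F-box genes and nuclear hormone receptors; without replicate 1 all 12 stayed. Shifting bound labels along genes kept 10, losing the same 2 lists (permutation adjusted p = 0.0678 and 0.261). Shifting summits kept 8 and also passed histones, meiosis, splicing and spermatogenesis-defective genes; shifted summits seldom meet a promoter, which raises ratios: F-box genes reached 1.50, nuclear hormone receptors 1.53, collagens 1.09 and homeobox genes 1.14 times the shifted mean. Other reversals were in lists outside the 12, with few bound members; the cause was not tested. With the 825 strongest peaks, intestine and meiosis genes had an odds ratio of 0. In the narrow window, neuron and splicing genes had an odds ratio of 0. Histones had 0.725 by nearest 5′ end. With 1 replicate left out, odds ratios ran from 0.542 to 1.34 for histones, 0 to 3.61 for meiosis and 0 to 2.24 for neuron genes. No paired analysis was possible because there is a single group. With read depth unknown, weak sites missing from these lists cannot be called unbound.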

Other observations

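The screen of gene families, the placement of tRNA summits in promoter windows, the X comparison of tRNA genes, the counts around athp-1 and the comparison of 3′ UTR shares across ranks were chosen after the results were seen.

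Among 175 families of genes with a shared symbol prefix and at least 10 members, 9 passed Fisher's exact test after Benjamini-Hochberg adjustment, 7 with more binding and 2 with less. The 2 families with more binding that had no member in a fixed list were the J-domain co-chaperones and the kinesins. Of 29 dnj genes, 7 were bound (24.1%; odds ratio 6.47, 95% interval 2.33 to 15.7, exact test adjusted p = 0.0111), with dnj-13 strongest at a signal of 355. Of 13 klp genes, 4 were bound (30.8%; odds ratio 9.02, 95% interval 2.03 to 32.4, exact test adjusted p = 0.0484): klp-7, klp-16, klp-18 and klp-19, which encode motors of the mitotic or meiotic spindle. Subunits of the vacuolar proton pump, of which only vha-6 was in a fixed list, also passed, with 5 of 20 vha genes bound (odds ratio 6.77, 95% interval 1.92 to 19.7, exact test adjusted p = 0.0484). Nucleoporins had 5 of 26 npp genes bound and did not pass (exact test adjusted p = 0.0890). The family calls were not repeated in the narrower promoter window or by nearest 5′ end, so whether they would hold there was not tested. The summit counted for dnj-19 is the same as that of nhr-47, at 5505226 on chromosome V.

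The window of 20 kb around athp-1 was not crowded with regions in all lists. It held 22 summits in the pooled list, 28 in replicate 1 and 20 in replicate 2, more than 60.9%, 87.6% and 53.7% of windows of the same width on chromosome III. In replicate 1 the summits inside the gene included coding exons at 10888935, 10885233 and 10892750 (ranks 621, 1559 and 1779). These counts were made to ask whether extra copies of the transgene crowd the window in every list, which they did not show. The question was not pursued, since a number of regions is a poor measure of copy number and the extent of the transgene is not given in the sources used here.

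The binding of tRNA genes is a pattern that shared reads could produce, since many tRNA genes have identical copies. Among the 140 tRNA genes whose sequence occurs once in the genome, 25.7% were bound (exact binomial 95% interval 18.7 to 33.8%). That is far above the 5.23% reached by the highest of the shifts over all tRNA genes. Only exact copies were counted, so a gene a few bases from another still counted as single. A summit within 200 bp could also belong to a neighbouring tRNA gene. These values thus cannot decide whether shared reads are the whole cause. The share was 47.8% for the 404 genes with 5 or more copies, so shared reads may still add to the count. Overlap with bound promoters accounts for few sites, since 15.7% of the 223 summits near tRNA genes lay in a promoter window (exact binomial 95% interval 11.2 to 21.1%). Whether other tagged proteins or untagged worms give the same signal was not analysed here, and no biological explanation was tested.

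The low share of bound genes on X might come from weaker signal over the whole chromosome, or from promoter composition. X-linked tRNA genes were bound as often as autosomal ones, 116 of 276 and 141 of 336 (odds ratio 1.00, 95% interval 0.717 to 1.40, Fisher's exact test p = 1). That interval lies above that of the protein-coding genes, 0.179 to 0.354. It cannot decide whether signal was weaker along X, since 404 tRNA genes have 5 or more copies and single-copy genes were not compared alone. Reads shared between copies on X and on the autosomes could make the shares alike. Promoters on X had a slightly higher mean GC content than those on autosomes, 36.0% and 35.2%. Genes were split into 10 strata by rank of promoter GC content. Bound autosomal genes made up 1.10% of the stratum lowest in GC and 10.2% of the highest, so the GC difference would favour binding on X. Within the strata the pooled odds ratio of X to autosomes was 0.225 (Mantel-Haenszel 95% interval 0.162 to 0.313). GC content thus does not account for the low share of bound protein-coding genes on X. No biological explanation was tested.

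Replicate 1 had a larger share of summits in 3′ UTRs than replicate 2, 7.76% (exact binomial 95% interval 6.52 to 9.16%) and 3.82% (2.95 to 4.86%) of the 1649 strongest regions. If one list merely reached deeper, replicate 2 might match replicate 1 at another rank, but from its 500 to its 5000 strongest regions its share rose from 2.40% to no more than 5.34% (exact binomial 95% interval 4.73 to 6.00%), and over all 30000 regions it was 3.76% (3.91% for replicate 1). This argues against lists that differ only in how far down the ranks they reach. It does not test read depth, which is unknown and could change which regions rank highest. The share of replicate 1 fell from 8% of its 1000 strongest regions to 6.4% of its 5000 strongest (exact binomial 95% interval 5.74 to 7.11%), which overlaps that of replicate 2, and at equal ranks the gap shrank from 5.00 to 1.06 points. The difference is thus one of the strongest regions, and unequal read depth stays open as a cause. Signal along very highly transcribed genes stays open: 1.56% of the 128 replicate 1 summits in 3′ UTRs (exact binomial 95% interval 0.190 to 5.53%) fell in ribosomal protein, vitellogenin, collagen, muscle or heat shock genes, which are 1.40% of all genes, and so few summits cannot decide it. No biological explanation was tested.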
